A study of Homo sapiens with 12 samples.

How the data were processed

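Gene expression was measured on 12 Affymetrix human gene arrays, each hybridised with total RNA from a patient-derived luminal breast tumor grown in mice. The values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the deposited log2 values came from Partek with RMA, a method that corrects background, makes the arrays' distributions alike and summarises the probes of a set; no version is given in the sources used here. That the values are on the log2 scale with no centring of genes was read from the values themselves, which ran from 2.06 to 13.10 with array medians between 5.27 and 5.36. The genome build and the detection of each probe above background are not given in the sources used here. The number of arrays, 3 per group, limits the precision of every difference.

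Probes were named through the platform annotation supplied with the values. Of 33297 probes, 19181 had 1 gene symbol, 2055 had several and 12061 had no listed gene. Of the probes with 1 symbol, 19143 matched a current gene record by Entrez identifier, and 0 symbols needed an update. The 25 probes of Y-linked genes and XIST were left out. Each of the 17934 remaining genes was represented by its probe with the highest mean over the 12 arrays, which was a choice among probes for 894 genes. No gene was removed for a low level. Probes with several symbols or none entered no comparison of named genes and were tested apart. The array hybridises human transcripts, so mouse host cells are visible only through cross-hybridisation.

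Arrays were grouped by the labels into placebo, estradiol (E2), E2 with medroxyprogesterone acetate (MPA) and E2 with progesterone (P4), with 3 arrays in each. One linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The model had 8 residual degrees of freedom, to which the variance prior added 2.52. The comparisons were E2 against placebo, E2+MPA against E2, E2+P4 against E2, E2+MPA against E2+P4, and each combined treatment against placebo. All tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Confidence intervals are 95% intervals from the same moderated test. Replicate numbers did not enter the model.

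Gene lists were fixed before the data were examined, and 24 with at least 5 measured members were tested. They covered hormone response (estrogen-induced, estrogen-repressed, progestin-induced, glucocorticoid-induced and androgen-induced genes) and growth (mitosis, DNA replication, RNA polymerase III, cytosolic tRNA synthetase and ribosome biogenesis genes). They also covered metabolism and stress (cholesterol synthesis, fatty acid synthesis, unfolded protein response, hypoxia, interferon-stimulated and immediate-early genes) and milk and secretory genes. Cell type lists held luminal epithelial, basal epithelial, fibroblast, endothelial, leukocyte, adipocyte and skeletal muscle markers. A list of red cell markers had 4 measured members and was not tested. Some genes belong to more than 1 list, such as NDRG1 in the progestin-induced, androgen-induced and hypoxia lists. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Beside it stand camera with a correlation estimated from the arrays and fry, whose directional test asks whether the genes of a list move one way on balance and whose mixed test asks whether they change in either direction.

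The genes named in the text followed a rule fixed before the data were examined. It took a panel of hormone receptors and their targets in every comparison, the largest changes among genes past the threshold, the 5 genes of smallest p in a direction where fewer than 5 passed, and for each list the members of smallest p. FKBP5, which was on the panel, had no probe with a single symbol and is not analysed here. Symbols that stand for uncharacterised loci or small RNAs were skipped by the same rule, and genes named outside it are said to be so.

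Correlations between the log2 differences of comparisons that share arrays were set beside 200 simulated draws of unchanged groups sharing the same arrays. The model and the list test were tested on simulated data with the real genes' means and within-group spreads and independent genes, in which 200 of 17934 genes were changed. For E2 against placebo, 80% of 100 genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered. For E2+MPA against E2 these shares were 84% and 99%, for E2+P4 against E2 72% and 97%, and for E2+MPA against E2+P4 83% and 99%. Unchanged genes called in these simulations numbered 14, 10, 10 and 9. A list shifted by 0.5 was called in each of these 4 simulations, with 0 other lists called. Because the simulated genes were independent, this does not show how often camera calls unchanged lists whose genes vary together. Members of several lists did vary together here, with a mean correlation between pairs of up to 0.538 in the interferon list.

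Alternatives fixed before the data were examined were 3 other normalizations (quantile normalization again, cyclic loess and centring on the 75th percentile), a filter on dim genes, the mean of a gene's probes, every probe on its own, a fit to only the groups compared, a variance prior with trend and robust estimation, array weights, the replicate number as a block, 2 other thresholds, and each array left out in turn. Alternatives chosen after seeing the data were leaving out the pair of arrays with the highest correlation, a test for any difference among the 4 groups, both progestin groups against the other groups, and array weights estimated gene by gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, using pandas 2.3.3.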

Results

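Gene expression was profiled in a luminal breast cancer taken from a patient and carried as a xenograft in NSG mice, an immunodeficient strain that accepts human tissue. Small tumor pieces were implanted, and the mice received silastic pellets that released placebo, the estrogen estradiol (E2), E2 with the synthetic progestin medroxyprogesterone acetate (MPA), or E2 with the natural hormone progesterone (P4). Each of the 4 groups had 3 arrays, 12 in all, and 17934 human genes were compared as log2 signals. Doses and the length of treatment are not given in the sources used here. The labels call the arrays of a group replicates without saying that each came from its own animal, so p-values measure the spread between these samples, which may in part be technical. With 3 arrays per group, the 95% confidence interval of a gene's log2 difference reached 0.29 to either side at the median gene.

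The progesterone receptor gene PGR, a classical target of estradiol through the estrogen receptor, did not follow the labels. It measured 5.66, 6.62 and 8.37 on the 3 arrays labelled placebo and 7.91, 6.74 and 6.63 on those labelled E2, so the highest level of all 12 arrays stood in the placebo group. GREB1, another estrogen receptor target, measured 9.38, 9.21 and 10.45 on the placebo arrays and 10.46, 10.08 and 9.92 on the E2 arrays. ESR1, which encodes the estrogen receptor, was high throughout, at 10.25 ± 0.27 (SD, n = 3) in placebo and 10.33 ± 0.44 (SD, n = 3) in E2. Of the 12 arrays, 4 had their closest array in their own group. The median correlation across genes was 0.9832 within groups and 0.984 between groups, and genes are not independent replicates. The array labelled placebo replicate 3 and the array labelled E2+MPA replicate 1 had the highest correlation of all 66 pairs, 0.9972, and E2+P4 replicate 3 had the lowest mean correlation with the others, 0.9711. Groups accounted for 31.2% of the total variance, where unrelated groups would on average hold 27.3%. For these reasons the groups are called by their labels throughout.

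**Figure D1:**
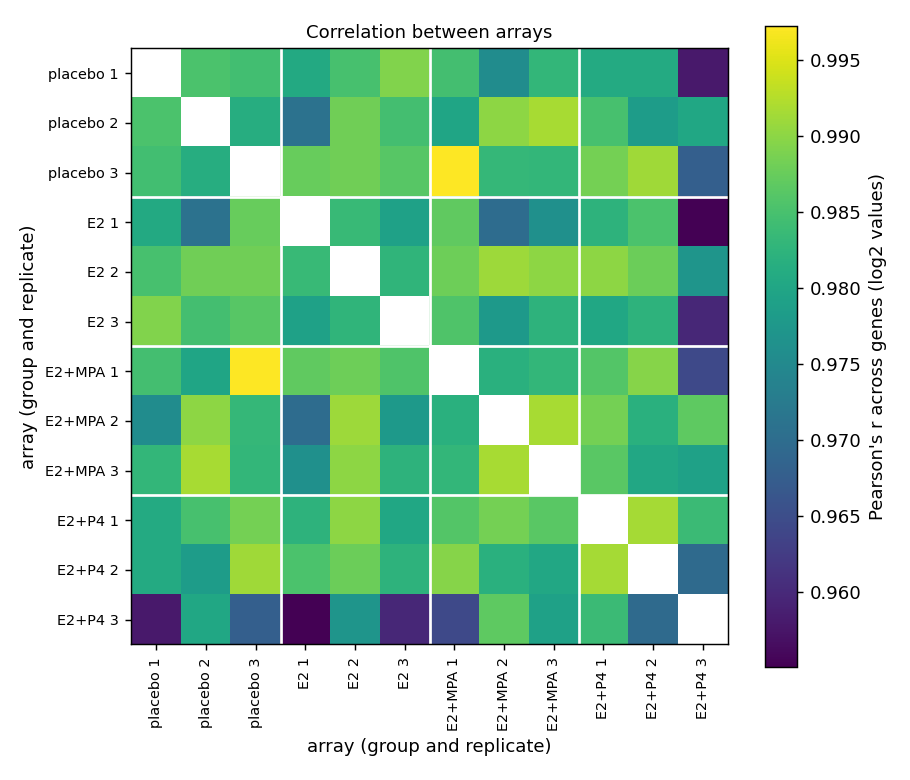
Pearson's r across genes between each pair of the 12 arrays (both axes: arrays by group and replicate; color: r of log2 values; white lines part the groups). The brightest cell off the diagonal joins placebo replicate 3 and E2+MPA replicate 1, and arrays of one group do not form blocks.

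**Figure D2:**
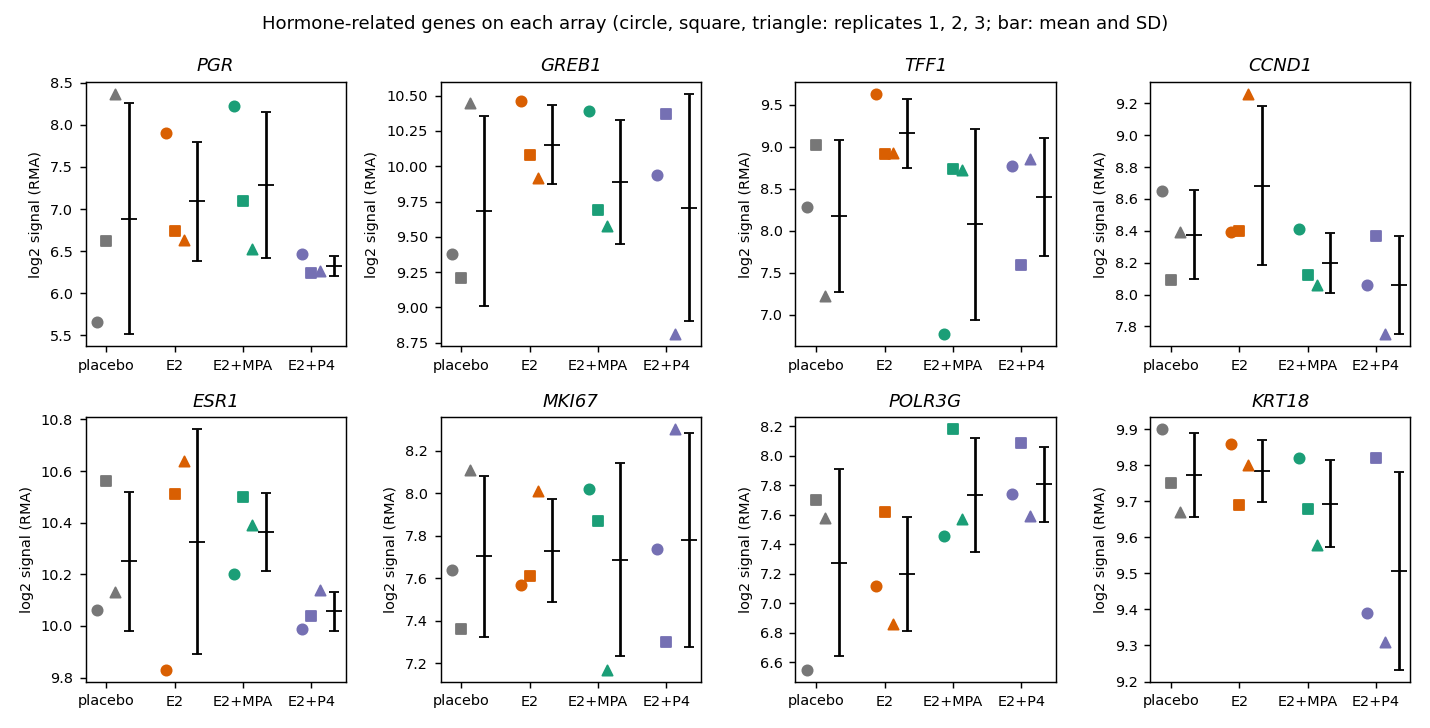
Log2 signal (RMA) of 8 hormone-related genes on each array (circles, squares and triangles are replicates 1, 2 and 3; the black bar is the mean with its SD, n = 3) by labelled group on the horizontal axis. PGR ranged from 5.66 to 8.37 within the placebo group, and POLR3G had its lowest mean, 7.20, in the E2 group.

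E2 against placebo asks what estradiol alone did to the tumor. Estrogen-induced genes were higher as a list in the arrays labelled E2. Of 40 measured members 33 had the higher mean, with a median difference of 0.24 (log2; camera adjusted p = 0.000127, and adjusted p = 0.517 with an estimated correlation). TFF1, a secreted trefoil peptide, measured 9.16 ± 0.41 in E2 against 8.18 ± 0.91 in placebo (SD, n = 3 each), MYBL1, a transcription factor of the MYB family, 10.57 ± 0.20 against 10.08 ± 0.51, and MLPH 9.16 ± 0.42 against 8.76 ± 0.23. Interferon-stimulated genes were also higher as a list, with 26 of 29 members at the higher mean and a median difference of 0.31 (camera adjusted p = 3.17e-07, and adjusted p = 0.705 with an estimated correlation). IFI6 measured 10.24 ± 0.33 in E2 against 9.20 ± 0.55 in placebo, and BST2, a membrane protein that tethers viruses, 7.85 ± 0.09 against 7.16 ± 0.13.

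No single gene passed in E2 against placebo with limma. The count was 0 of 17934, with a smallest adjusted p of 0.998, and 483 genes (2.69%) had an unadjusted p under 0.05. Without placebo replicate 3 the count was 1. In 6.5% of genes the arrays of the groups did not overlap, where chance gives 10% on average. The genes of smallest p on the higher side were TRAM2, at 7.45 ± 0.12 against 6.89 ± 0.06, then OPRD1, an opioid receptor, with a difference of 0.51, AKR7A3, an aldo-keto reductase, with 0.66, MAST4 with 0.80 and the fatty acid elongase ELOVL5 with 0.37. On the lower side they were DNAI7, at 3.66 ± 0.14 against 4.24 ± 0.11, then RETREG1, an endoplasmic reticulum autophagy receptor, with −0.93, HACL1 with −0.34, KRTAP5-5 with −0.31 and MRRF, a mitochondrial ribosome factor, with −0.38. None of these 10 passed. Differences on the panel were 0.21 for PGR (95% CI −1.19 to 1.61), 0.47 for GREB1 (−0.46 to 1.40), 0.98 for TFF1 (−0.33 to 2.30), 0.31 for the cyclin gene CCND1 (−0.24 to 0.85), 0.16 for MYC, 0.03 for the proliferation marker MKI67, 0.08 for ESR1, 0.10 for the glucocorticoid receptor gene NR3C1, 0.11 for WNT4, 0.02 for TNFSF11, −0.09 for KRT5, 0.01 for KRT18 and −0.08 for POLR3G, a subunit of RNA polymerase III.

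The other 22 lists were not called in E2 against placebo, with camera adjusted p values from 0.109 to 0.8. Median differences were 0.09 for progestin-induced genes, 0.09 for glucocorticoid-induced genes, −0.01 for androgen-induced genes, −0.002 for estrogen-repressed genes, −0.105 for mitosis genes, −0.003 for DNA replication genes and 0.045 for RNA polymerase III genes. They were 0.01 for cytosolic tRNA synthetase genes, 0.03 for ribosome biogenesis genes, 0.16 for cholesterol synthesis genes, 0.12 for fatty acid synthesis genes, 0.06 for unfolded protein response genes, −0.01 for hypoxia genes, 0.10 for immediate-early genes and 0.01 for milk and secretory genes. Among cell type markers they were 0.05 for luminal epithelial, −0.05 for basal epithelial, −0.01 for fibroblast, 0.008 for endothelial, −0.03 for leukocyte, 0.07 for adipocyte and 0.02 for skeletal muscle markers. Median, mean and test differed in sign for the androgen-induced, hypoxia, milk and secretory and basal epithelial lists. Adjusted over the list alone, 1 fatty acid synthesis gene passed, ELOVL5, and 0 genes did in each other list; over all genes the count was 0 in every list. Fry called 0 lists, with a smallest directional adjusted p of 0.944. Without E2 replicate 2 the interferon list had a median difference of 0.115 and was no longer called (camera adjusted p = 0.173), while the estrogen-induced list stayed called whichever of the 6 arrays was left out, with a largest adjusted p of 0.0164. Its mean levels on the arrays nonetheless overlapped, at 8.174, 7.792 and 7.905 in E2 against 7.658, 7.588 and 7.895 in placebo, with E2 replicate 1 the highest.

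**Figure D3:**
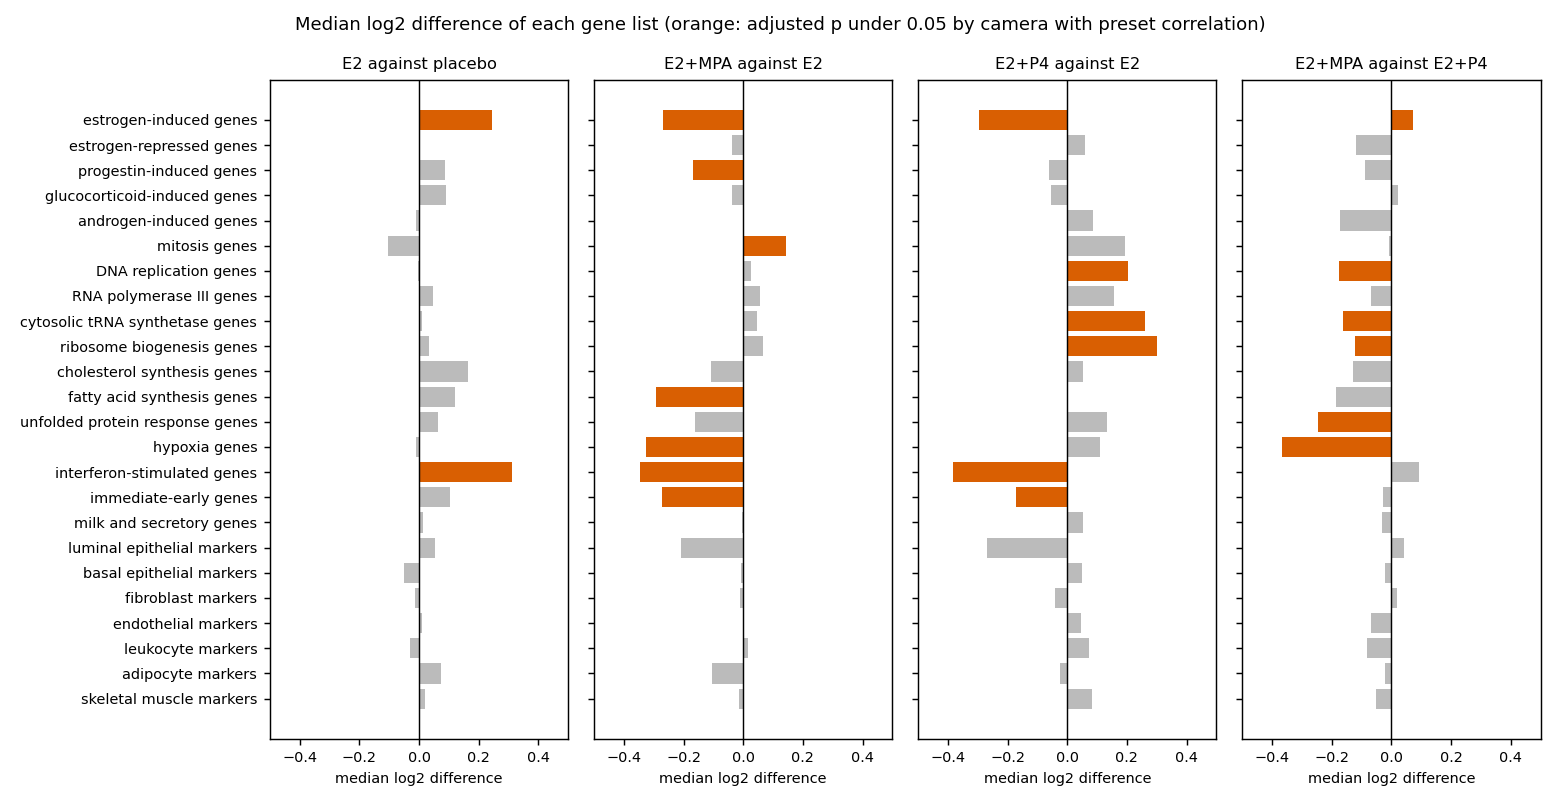
Median log2 difference of each of the 24 gene lists (rows of the vertical axis) in 4 comparisons (panels), on a horizontal axis of log2 difference. Orange bars passed an adjusted p of 0.05 by camera with the preset correlation; estrogen-induced genes lay at 0.24 for E2 against placebo, −0.27 for E2+MPA against E2 and −0.295 for E2+P4 against E2. These comparisons share the E2 arrays, so their values are not independent, and a list high on those arrays alone would show these signs.

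E2+MPA against E2 asks what a synthetic progestin adds when estradiol is present. Estrogen-induced genes were lower as a list with MPA, with 32 of 40 members at the lower mean and a median difference of −0.27 (camera adjusted p = 0.0126, and adjusted p = 0.621 with an estimated correlation). The same E2 arrays enter E2 against placebo, so a list that happened to be high on them would be higher there and lower here. EGR3, an early growth response factor, measured 4.75 ± 0.10 in E2+MPA against 5.07 ± 0.14 in E2 (SD, n = 3 each), and CCND1 8.20 ± 0.19 against 8.68 ± 0.50. Progestin-induced genes were lower, not higher, with 20 of 25 members at the lower mean and a median of −0.17 (camera adjusted p = 0.00794, and adjusted p = 0.621 with an estimated correlation). In that list IRS2, an insulin receptor substrate, differed by −0.37 and NDRG1, which also responds to hypoxia, by −0.58. Mitosis genes were higher by a median of 0.145 with 23 of 32 members up (camera adjusted p = 0.00391, and adjusted p = 0.63 with an estimated correlation), among them the spindle gene ASPM at 8.27 ± 0.18 against 7.69 ± 0.33 and the kinetochore gene CENPF at 9.0 ± 0.19 against 8.44 ± 0.30.

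Hypoxia genes were lower in E2+MPA by a median of −0.33, with 20 of 21 members at the lower mean (camera adjusted p = 0.00028, and adjusted p = 0.621 with an estimated correlation); PFKFB4, a regulator of glycolysis, differed by −0.69. Interferon-stimulated genes were lower by a median of −0.35 with 23 of 29 members down (camera adjusted p = 0.00353, and adjusted p = 0.63 with an estimated correlation), with BST2 at −0.72 and the transcription factor IRF7 at −0.36. Fatty acid synthesis genes were lower by a median of −0.29 (14 of 17 members; camera adjusted p = 0.0117, and adjusted p = 0.621 with an estimated correlation), with the desaturase SCD at 10.30 ± 0.04 against 10.63 ± 0.13 and DGAT2, which makes triglycerides, at −0.29. Immediate-early genes were lower by a median of −0.27 (14 of 16 members; camera adjusted p = 0.012, and adjusted p = 0.621 with an estimated correlation), although ATF3 in that list was at 0.31. None of these member genes passed on its own, and adjusted over the list alone 0 genes passed in each of the 24 lists.

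No gene passed in E2+MPA against E2 with limma: 0 of 17934, with 1063 (5.93%) at an unadjusted p under 0.05. The arrays did not overlap in 11% of genes, where chance gives 10% on average. The smallest adjusted p, 0.501, belonged to CHRNA7, a nicotinic receptor subunit, at 4.93 ± 0.15 against 5.58 ± 0.04. Next on the lower side came FAM27B at −0.64, OPRD1 at −0.55, the amino acid transporter SLC1A4 at −0.52 and RTBDN at −0.63. On the higher side stood the kinase gene MAPK10 at 7.98 ± 0.12 against 7.03 ± 0.20, the chromatin protein gene HMGB1 at 0.48, UBE2Q2P1 at 0.46, ZNF596 at 0.41 and RRP15, a ribosome maturation factor, at 0.47; none passed. Panel differences were 0.19 for PGR (95% CI −1.21 to 1.60), −0.27 for GREB1, −1.08 for TFF1 (−2.40 to 0.24), −0.49 for CCND1 (−1.03 to 0.06), −0.01 for MYC, −0.04 for MKI67, 0.04 for ESR1, 0.20 for NR3C1, −0.18 for WNT4, −0.05 for TNFSF11, 0.09 for KRT5, −0.09 for KRT18 and 0.54 for POLR3G (−0.16 to 1.24).

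The other 17 lists were not called in E2+MPA against E2, and the smallest camera adjusted p among them was 0.0944. Median differences were −0.04 for estrogen-repressed genes, −0.04 for glucocorticoid-induced genes, 0 for androgen-induced genes, 0.03 for DNA replication genes, 0.06 for RNA polymerase III genes, 0.05 for cytosolic tRNA synthetase genes, 0.065 for ribosome biogenesis genes and −0.11 for cholesterol synthesis genes. They were −0.16 for unfolded protein response genes, −0.005 for milk and secretory genes, −0.21 for luminal, −0.007 for basal, −0.01 for fibroblast, −0.002 for endothelial, 0.02 for leukocyte, −0.10 for adipocyte and −0.01 for skeletal muscle markers. Median, mean and test differed in sign for the milk and secretory, basal, leukocyte and skeletal muscle lists. Fry called 0 lists by direction (smallest adjusted p 0.392), and its mixed test called the endothelial list (adjusted p = 0.00033), in which ROBO4 was at −0.24 and CLDN5 at −0.25. The mean level of that list was low, between 4.313 and 4.366 on these arrays. Its median SD within groups was 0.077, against 0.113 in random lists of matched level, so small differences weigh more in this test. The call is therefore not read as a response of endothelial cells.

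Several list calls of E2+MPA against E2 ended when 1 array was left out. Without E2 replicate 1 this held for the estrogen-induced (median −0.064, adjusted p = 0.122), progestin-induced (−0.08, 0.122), mitosis (0.051, 0.182), hypoxia (−0.18, 0.122) and immediate-early lists (−0.11, 0.224). Without E2 replicate 2 the median of the interferon list went from −0.35 to −0.04 (adjusted p = 0.659). Without E2 replicate 3 the fatty acid list went from −0.29 to −0.097 (0.243), whereas the estrogen-induced list kept its median at −0.27 (0.064). Without E2+MPA replicate 1 calls ended for the estrogen-induced (−0.31, 0.0801), progestin-induced (−0.115, 0.226) and interferon lists (−0.215, 0.32), and without E2+MPA replicate 2 for the mitosis (0.10, 0.0916) and immediate-early lists (−0.11, 0.0789). With dim genes left out, the progestin-induced (−0.147, 0.211), fatty acid (−0.33, 0.0577) and immediate-early lists (−0.298, 0.139) were not called. With both arrays of the closest pair left out, the estrogen-induced (−0.31, 0.0593), progestin-induced (−0.115, 0.272) and interferon lists (−0.215, 0.273) were not called.

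E2+P4 against E2 asks the same of the natural hormone. MYO15B, a gene of the unconventional myosin family, fell by 1.11 on the log2 scale and was the only gene of 17934 past the threshold with limma. It measured 5.64 ± 0.12 in E2+P4 against 6.75 ± 0.07 in E2 (SD, n = 3 each; SE of the difference 0.093, adjusted p = 0.00325), lower on 3 of 3 arrays. Of its other probes, one differed by −0.79 with 3 of 3 arrays lower; the other, also at −0.79, had overlapping arrays, at 6.15, 6.65 and 4.99 against 6.51, 6.45 and 7.21. Genes that make proteins and ribosomes were higher as lists. Cytosolic tRNA synthetase genes, whose products load tRNAs with amino acids, had 18 of 20 members at the higher mean and a median of 0.26 (camera adjusted p = 0.000255, and adjusted p = 0.604 with an estimated correlation). SARS1 measured 8.28 ± 0.13 against 7.82 ± 0.03 and EPRS1 9.28 ± 0.13 against 8.70 ± 0.17. Ribosome biogenesis genes had 23 of 26 members at the higher mean and a median of 0.30 (camera adjusted p = 0.000494, and adjusted p = 0.604 with an estimated correlation), with WDR12 at 8.21 ± 0.07 against 7.59 ± 0.23 and DKC1, which modifies ribosomal RNA, at 9.03 ± 0.14 against 8.46 ± 0.10. With 1 array left out the ribosome call came close to the threshold, with a largest camera adjusted p of 0.0448. The mean levels of that list were 8.135, 8.263 and 8.02 in E2+P4 against 8.004, 7.979 and 7.732 in E2.

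DNA replication genes were higher in E2+P4 by a median of 0.20, with 30 of 38 members up (camera adjusted p = 0.00587, and adjusted p = 0.604 with an estimated correlation); the clamp loader subunit RFC3 differed by 0.51 and the helicase subunit MCM6 by 0.42. RNA polymerase III genes, whose products transcribe tRNA genes, had 20 of 28 members at the higher mean and a median of 0.16, which was not called (camera adjusted p = 0.24). Among them POLR3C measured 8.36 ± 0.03 against 8.05 ± 0.07, POLR3G 7.81 ± 0.26 against 7.20 ± 0.39, and SNAPC2 differed by −0.62. Estrogen-induced genes were lower as a list, with 32 of 40 members down and a median of −0.295 (camera adjusted p = 3.26e-05, and adjusted p = 0.39 with an estimated correlation). This call held whichever of the 6 arrays was left out, with a largest camera adjusted p of 0.000786. The mean levels of the list overlapped, at 7.824, 7.777 and 7.501 in E2+P4 against 8.174, 7.792 and 7.905 in E2, with E2 replicate 1 the highest. EGR3 differed by −0.45 and the microtubule gene MAPT, in the same list, by 1.54. Interferon-stimulated genes were lower by a median of −0.38 with 25 of 29 members down (camera adjusted p = 3.26e-05, and adjusted p = 0.604 with an estimated correlation), with ISG15 at −0.60 and OAS3 at −0.85. The estrogen-induced and interferon lists were higher in E2 against placebo, which uses the same E2 arrays, so the opposite signs are not independent results. Immediate-early genes were lower by a median of −0.17 (camera adjusted p = 0.0118, and adjusted p = 0.604 with an estimated correlation). Over all genes 0 members passed in every list; adjusted over the list alone, 2 tRNA synthetase genes, 3 ribosome biogenesis genes, 1 immediate-early gene and 2 estrogen-repressed genes passed.

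At an unadjusted p under 0.05 there were 2241 genes (12.5%) in E2+P4 against E2. The arrays did not overlap in 16.3% of genes, where chance gives 10% on average. Genes vary together here, so by chance such shares can lie well off their average in either direction. At an adjusted p under 0.10 the count was 6, with 1 higher and 5 lower. Next to MYO15B the lower side held the actin-binding protein gene PFN1, at 9.50 ± 0.02 against 10.06 ± 0.04, SELENBP1 at −0.81, RTBDN at −0.85, PISD, which makes phosphatidylethanolamine in mitochondria, at −0.66 and LIN37 at −0.54. The higher side held PALLD, a gene of the actin cytoskeleton, at 7.39 ± 0.25 against 6.25 ± 0.24, RPIA of the pentose phosphate pathway at 0.56, HACL1 at 0.46, ACTR8 at 0.62 and GPR155 at 1.02; none of these 10 passed at an adjusted p of 0.05. Panel differences were −0.77 for PGR (95% CI −2.18 to 0.63), −0.45 for GREB1 (−1.38 to 0.48), −0.76 for TFF1 (−2.07 to 0.56), −0.62 for CCND1 (−1.17 to −0.08, adjusted p = 0.359), −0.27 for ESR1, −0.08 for MYC, 0.05 for MKI67, 0.15 for NR3C1, 0.08 for WNT4, −0.05 for TNFSF11, −0.003 for KRT5, −0.28 for KRT18 and 0.61 for POLR3G (−0.09 to 1.31).

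The 18 lists not called in E2+P4 against E2 had camera adjusted p values of 0.0533 or more. Their medians were 0.06 for estrogen-repressed, −0.06 for progestin-induced, −0.05 for glucocorticoid-induced, 0.09 for androgen-induced, 0.195 for mitosis, 0.05 for cholesterol synthesis, 0 for fatty acid synthesis, 0.13 for unfolded protein response, 0.11 for hypoxia and 0.05 for milk and secretory genes. For markers they were −0.27 for luminal, 0.05 for basal, −0.04 for fibroblast, 0.05 for endothelial, 0.07 for leukocyte, −0.02 for adipocyte and 0.08 for skeletal muscle lists. Median, mean and test differed in sign for the estrogen-repressed, progestin-induced, cholesterol synthesis and hypoxia lists, and the median of the fatty acid list was 0. Fry called 0 lists by direction (smallest adjusted p 0.109), and its mixed test called the estrogen-repressed, tRNA synthetase and endothelial lists (adjusted p = 0.0215 for each). The low level and small SD of the endothelial list, given above, limit that call too. MYO15B was not called with the mean of its probes (−0.90, adjusted p = 0.16) or in a fit to only the groups compared (adjusted p = 0.284), and the count of 1 gene became 2 without E2 replicate 1, E2+P4 replicate 2 or E2+P4 replicate 3 and 4 without E2 replicate 2. It was 2 with every probe on its own, 5 with array weights estimated gene by gene and 498 with array weights whose estimate did not converge. Without E2 replicate 2 the median of the interferon list went from −0.38 to −0.045 (adjusted p = 0.0866), so most of that difference came from 1 array. The DNA replication call was lost without E2 replicate 1 (median 0.114, adjusted p = 0.26) or E2+P4 replicate 2 (0.201, 0.0865). That of immediate-early genes was lost without E2 replicate 1 (−0.048, 0.288), without E2+P4 replicate 3 (−0.074, 0.125) and with dim genes left out (−0.358, 0.114).

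E2+MPA against E2+P4 compares the progestins directly. MPA carries a methyl and an acetoxy group that progesterone lacks, and the doses of the pellets are not given in the sources used here, so matched doses cannot be assumed. Hypoxia genes were lower with MPA than with P4, with 20 of 21 members at the lower mean and a median of −0.37 (camera adjusted p = 0.000883, and adjusted p = 0.581 with an estimated correlation). NDRG1 measured 9.52 ± 0.08 in E2+MPA against 10.41 ± 0.15 in E2+P4 (SD, n = 3 each) and the glycolytic enzyme gene PGK1 10.18 ± 0.15 against 10.62 ± 0.11. Unfolded protein response genes were lower with MPA by a median of −0.25 (18 of 21 members; camera adjusted p = 0.00438, and adjusted p = 0.581 with an estimated correlation), with MANF at −0.34 and the disulfide isomerase PDIA6 at −0.52. Cytosolic tRNA synthetase genes were lower by a median of −0.16 (17 of 20 members; camera adjusted p = 0.00892, and adjusted p = 0.581 with an estimated correlation), with SARS1 at −0.44 and MARS1 at −0.28.

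DNA replication genes were lower with MPA than with P4 by a median of −0.18 (31 of 38 members; camera adjusted p = 0.00892, and adjusted p = 0.726 with an estimated correlation), with CHAF1B at −0.44 and MCM4 at −0.26. Ribosome biogenesis genes were lower by a median of −0.12 (24 of 26 members; camera adjusted p = 0.0241, and adjusted p = 0.726 with an estimated correlation), with WDR12 at −0.51 and DKC1 at −0.38. Estrogen-induced genes were higher by a median of 0.07 (23 of 40 members; camera adjusted p = 0.0352, and adjusted p = 0.581 with an estimated correlation), with RERG at 0.40 and MAPT at −1.55. Adjusted over the list alone, 1 gene each of the estrogen-repressed, androgen-induced, tRNA synthetase and fatty acid synthesis lists passed, as did 2 cholesterol synthesis genes, of which SQLE, an enzyme of sterol synthesis, had the smallest p at 9.11 ± 0.09 against 9.53 ± 0.18. Over all genes the count was 0 in every list.

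For single genes, 0 of 17934 passed between the progestins with limma, 2 had an adjusted p under 0.10 and 1701 (9.48%) an unadjusted p under 0.05. The arrays did not overlap in 14.6% of genes, where chance gives 10% on average and, since genes vary together, can give shares well off it. MYO15B was at 6.41 ± 0.12 in E2+MPA against 5.64 ± 0.12 in E2+P4, a difference of 0.77 (95% CI 0.57 to 0.98, adjusted p = 0.0758), and YPEL2 at 7.66 ± 0.07 against 8.27 ± 0.11 (adjusted p = 0.0758). Next in p came the cytokine gene IL18 at 0.61, H2AC14 at 0.96, ZNF718 at 0.88 and PFN1 at 0.42 on the higher side, and ACTR8 at −0.68, GPRC5A at −0.68, SUSD5 at −0.96 and ABHD2 at −1.24 on the lower side. The count of 0 was 1 with cyclic loess, 1 with a trend and robust prior, 9 with every probe on its own, 179 with array weights estimated gene by gene and 2330 with array weights whose estimate did not converge. The 95% interval of the difference between arrays of these labels lay within 1 log2 unit of 0 for 94.4% of genes, each gene taken alone. Genes of every level enter that share, dim ones included. Of the panel intervals given next, those of PGR, GREB1 and TFF1 reached beyond that bound and the others did not. Intervals on the panel were −0.44 to 2.37 for PGR, −0.75 to 1.11 for GREB1, −1.64 to 0.99 for TFF1, −0.41 to 0.68 for CCND1, −0.50 to −0.02 for WNT4, −0.77 to 0.63 for POLR3G, −0.14 to 0.75 for ESR1, −0.37 to 0.48 for NR3C1, −0.65 to 0.81 for MYC, −0.75 to 0.56 for MKI67, −0.12 to 0.31 for KRT5, −0.10 to 0.48 for KRT18 and −0.17 to 0.17 for TNFSF11.

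The 18 other lists were not called between the progestins, with camera adjusted p values of 0.0611 or more. Their medians were −0.12 for estrogen-repressed, −0.09 for progestin-induced, 0.02 for glucocorticoid-induced, −0.17 for androgen-induced, −0.007 for mitosis, −0.07 for RNA polymerase III, −0.13 for cholesterol synthesis, −0.19 for fatty acid synthesis, 0.09 for interferon-stimulated, −0.03 for immediate-early and −0.03 for milk and secretory genes. For markers they were 0.04 for luminal, −0.02 for basal, 0.02 for fibroblast, −0.07 for endothelial, −0.08 for leukocyte, −0.02 for adipocyte and −0.05 for skeletal muscle lists. Median, mean and test differed in sign for the glucocorticoid-induced, mitosis, immediate-early and adipocyte lists. Fry called 0 lists by direction (smallest adjusted p 0.0775), and its mixed test called the endothelial list (adjusted p = 0.0155), a call limited by the low level and small SD of that list. Without E2+MPA replicate 3 calls were lost for the estrogen-induced (median 0.118, adjusted p = 0.0625), DNA replication (−0.10, 0.16), tRNA synthetase (−0.138, 0.0587) and ribosome biogenesis lists (−0.034, 0.328). Without E2+P4 replicate 2 they were lost for the DNA replication (−0.149, 0.114) and ribosome biogenesis lists (−0.105, 0.264), and without E2+P4 replicate 3 for the unfolded protein response list (−0.21, 0.0636). The estrogen-induced call was also lost without E2+MPA replicate 1 (0.027, 0.124), with cyclic loess (0.102, 0.0721) and with both arrays of the closest pair left out (0.027, 0.129), and without E2+P4 replicate 3 its median turned to −0.036 (0.695).

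The log2 differences that MPA and P4 made against E2 correlated across genes at r = 0.617. Both comparisons use the same E2 arrays, and unchanged groups sharing them gave a median of 0.546 over 200 simulated draws (95% of draws between −0.285 and 0.918). The covariance was 0.0337 against a simulated median of 0.0155 (−0.0077 to 0.0785), so the shared arrays alone cover the observed value. The differences of E2 against placebo and of E2+MPA against E2 correlated at r = −0.574, beside a simulated median of −0.535 (−0.928 to 0.306), with a covariance of −0.0197 beside −0.0144 (−0.0769 to 0.0076). For P4 in place of MPA, r was −0.358, beside −0.575 (−0.929 to 0.291), with a covariance of −0.0159 beside −0.0155 (−0.0906 to 0.0071). Without placebo replicate 2 these values of r were −0.317 for MPA and −0.147 for P4, and for P4 r was −0.539 without placebo replicate 1 and −0.59 without E2 replicate 2. Genes are not independent replicates in these correlations, and 3 E2 arrays are too few to be split. No gene was called with both progestins; with 0 calls for E2+MPA that overlap could only be 0.

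Against placebo, E2+P4 changed 2 genes with limma. ERVMER34-1, an envelope gene of an endogenous retrovirus, rose from 4.39 ± 0.09 to 5.25 ± 0.13 (SD, n = 3 each; difference 0.87, SE 0.10, adjusted p = 0.0447); it lies outside the naming rule and was chosen after its values were seen. MYO15B fell from 6.61 ± 0.10 to 5.64 ± 0.12 (difference −0.97, SE 0.093, adjusted p = 0.0125). E2+MPA against placebo changed 0 genes, with a smallest adjusted p of 0.453. At an unadjusted p under 0.05 there were 1785 genes (9.95%) for E2+P4 and 542 (3.02%) for E2+MPA. The count of 2 for E2+P4 became 0 without placebo replicate 1, placebo replicate 2 or E2+P4 replicate 1 and 3 without E2+P4 replicate 2, and the count of 0 for E2+MPA became 2 without placebo replicate 3. With the mean of the probes of a gene, or in a fit to only the groups compared, the count for E2+P4 was 0, so both calls ended; it was 1 centred on the 75th percentile, with dim genes left out or with every probe on its own, 4 with quantile normalization again, 9 with array weights estimated gene by gene and 507 with array weights whose estimate did not converge.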

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

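The test for a difference among any of the 4 groups, the test of both progestin groups against the other groups, and the comparison of the closest pair of arrays were chosen after the results they bear on had been seen. Hypoxia genes stood out because the effect of MPA on them differed from that of P4 in a direct test, by a median of −0.367 (log2). The same held for unfolded protein response genes (−0.247), DNA replication genes (−0.177), cytosolic tRNA synthetase genes (−0.163), ribosome biogenesis genes (−0.122) and estrogen-induced genes (0.073). These are calls by camera with the preset correlation; with an estimated correlation the adjusted p values ran from 0.581 to 0.726, and fry called none of the 6 lists by direction. The estrogen-induced call held in 3 of 6 fits with 1 array left out, and its median turned to −0.036 without E2+P4 replicate 3. Probes with several gene symbols or none, which the report leaves aside, also had calls. What the probes without a listed gene measure is not given in the sources used here, so their calls are not read as changes of genes. Of 14116 such probes, 2 passed the threshold for E2+P4 against E2 (smallest adjusted p 0.0328) and 49 for E2+MPA against E2+P4 (smallest adjusted p 0.0147).

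PGR, GREB1 and other estrogen-induced genes differed widely between arrays of one label, while few genes followed the labels. The median SD of estrogen-induced genes within groups was 0.363, against 0.203 in random lists matched on level, and exceeded 100% of those lists. That argues against noise of equal size in all genes of a level. The lists were matched on level alone, so noise that differs between genes cannot be told from other variation by this value. The interferon list (0.412) and luminal markers (0.358) also exceeded 100% of their random lists, so a wide spread was not particular to estrogen targets. Within groups the estrogen-induced genes varied together little, with a mean correlation of 0.06 between pairs, against 0.002 in random lists. Labels attached to arrays other than those they describe stay open: 1 gene differed among the labelled groups (smallest adjusted p 0.0149), 10 of 100 random regroupings of the 12 arrays, the labels included, gave as many, and the highest other regrouping gave 127. That share would also arise if the treatments moved few genes. At an unadjusted p under 0.05 the labels gave 1464 genes in this test. Of the 100 regroupings, the labels included, 20 gave as many, and the highest other gave 3754. Tumors that differed in their exposure to hormone despite correct labels are a further explanation, which was not tested.

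The arrays labelled placebo replicate 3 and E2+MPA replicate 1 were closer than any other pair. Over all genes r was 0.9972 and the SD of their differences 0.1411, against 0.9917 and 0.2393 in the next pair. The SD of their differences over genes that vary among the other 10 arrays was 1.9 times that over stable genes of the same level, against a median of 2.81 in the other 65 pairs, which ran from 1.86 to 3.7. Both SDs, 0.226 and 0.119, were the lowest of all pairs, where the next lowest were 0.368 and 0.165. A small SD over stable genes raises the ratio. A ratio above 1.5 had been set beforehand as the value against one RNA sample or tumor piece on both arrays, and 1.9 lies above it; the ratio was also not the lowest of all, as one sample had been predicted to give. That bound was set aside only after the value was seen, because genes chosen for a large spread among arrays also include those measured with more noise, so that a shared sample would itself give a ratio above 1 by an amount that no pair known to share one can fix. With that, one RNA sample or piece on both arrays and separate, similar tumors cannot be told apart, while by the bound as first set the ratio argues against a shared sample.

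The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. For E2 against placebo the labels gave 0 genes, 10 of the 10 splits gave as many, and the highest other split gave 19. That split set placebo replicates 1 and 2 with E2 replicate 3 against the rest; it is the largest of 10, and no other split called a gene. The real count and the highest other were 0 and 0 for E2+MPA against E2 (10 splits as large), 1 and 0 for E2+P4 against E2 (1 split) and 0 and 0 for E2+MPA against E2+P4 (10 splits). They were 0 and 0 for E2+MPA against placebo (10 splits) and 2 and 0 for E2+P4 against placebo (1 split). For both progestin groups against the others the labels gave 0 genes (smallest adjusted p 0.49) and the highest other split gave 6. That 100 of 100 splits gave as many follows from the count of 0, as do the 10 of 10 above, and decides nothing.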

How the results depend on the processing

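Tests chosen after the results were seen were the test for any group difference, that of either progestin, leaving out the closest pair of arrays, and array weights estimated gene by gene; every alternative ran. The low counts were the least steady values. Of 96 list results 21 were called, and all 21 calls ended with an estimated correlation and with the directional test of fry. Over the alternatives in which lists were tested, 1286 list values stayed on their side of the threshold, most of them of lists that were not called. A further 44 newly passed, 79 no longer passed, and 3 turned direction and were called. Changes of direction in lists that were not called in the alternative were not counted. Lists were not tested with array weights, the trend and robust prior, every probe on its own, other thresholds or a fit to only the groups compared. The cause of the changes below was not tested, except that fewer arrays or genes enter where some are left out. Signal over background is not given in the sources used here, so dim genes were judged by level alone. With all arrays and the model of the report, counts were 2 genes for E2+P4 against placebo, 1 for E2+P4 against E2, 1 for any group difference and 0 in the other comparisons, and the progestin effects correlated at 0.617.

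Genes for E2+P4 against placebo were 4 with quantile normalization again, 1 centred on the 75th percentile, 1 with dim genes left out, 0 with the mean of the probes of a gene, 1 with every probe on its own, 0 in a fit to only the groups compared and 5 at adjusted p under 0.10. Genes for E2+P4 against E2 were 0 with the mean of the probes of a gene, 2 with every probe on its own, 0 in a fit to only the groups compared and 6 at adjusted p under 0.10. Genes for E2+MPA against E2+P4 were 1 with cyclic loess, 9 with every probe on its own, 1 with a trend and robust prior and 2 at adjusted p under 0.10. With every probe on its own the progestin effects correlated at 0.446. The test for any group difference gave 0 genes with both arrays of the closest pair left out.

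Array weights gave 498 genes for E2+P4 against E2, 2330 for E2+MPA against E2+P4 and 507 for E2+P4 against placebo, with correlations of 0.454 between the progestin effects and −0.428 between the E2 and the MPA effect. That estimate did not converge and gave E2+P4 replicate 1 a weight of 11.924, so the E2+P4 mean rested mostly on 1 array. Array weights estimated gene by gene, where that weight was 3.452, gave 5, 179 and 9 genes and a progestin correlation of 0.499.

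The replicate number as a block gave 0 genes for E2+P4 against placebo and changed no other count of genes, while mitosis genes and luminal markers became called in E2+P4 against E2. The numbers were not taken to pair the arrays, since not every pair of one number correlated above 0.1. After group means were removed, 18 pairs of the same number correlated at a median of 0.109 (−0.591 to 0.553, 9 of them over 0.1) and 36 other pairs at −0.018, and 4 of 12 arrays correlated best with their own number.

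With each array left out in turn, a group of 2 was assumed to vary like the others. Counts ran from 0 to 1 for E2 against placebo, 0 to 2 for E2+MPA against placebo, 0 to 3 for E2+P4 against placebo, 1 to 4 for E2+P4 against E2 and 0 to 2 for any group difference, and stayed at 0 otherwise. Correlations ran from 0.424 to 0.75 between the progestin effects, −0.755 to −0.317 between the E2 and the MPA effect and −0.59 to −0.147 between the E2 and the P4 effect. Without E2 replicate 1, a fit in which the direction of the camera test turned and the list became called, the median went from −0.003 to 0.083 for DNA replication genes in E2 against placebo, from −0.01 to −0.168 for hypoxia genes in E2 against placebo and from 0.11 to 0.225 for hypoxia genes in E2+P4 against E2. None of the 3 was called with all arrays, and the medians of the hypoxia list kept their sign. Over all arrays left out these medians ran from −0.119 to 0.091, −0.168 to 0.18 and −0.083 to 0.225.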

Other observations

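Genes named in this part were chosen after their values were seen, and none of them had an adjusted p under 0.05 in any comparison. BMPR1B, a receptor of bone morphogenetic proteins, varied most within groups, with a within-group SD of 2.16 against 0.164 for the median gene. It measured 9.60, 9.46 and 5.64 on the placebo arrays, 5.41, 5.39 and 10.70 on the E2 arrays, 5.79, 5.86 and 9.29 on the E2+MPA arrays and 5.67, 6.12 and 6.73 on the E2+P4 arrays. AGTR1, an angiotensin receptor gene, measured 10.77, 9.44 and 6.71 in placebo, 7.46, 5.15 and 10.23 in E2, 6.50, 5.31 and 9.02 in E2+MPA and 4.93, 4.81 and 5.49 in E2+P4. Both were thus highest on placebo replicates 1 and 2, E2 replicate 3 and E2+MPA replicate 3. CA2, a carbonic anhydrase gene, was lowest on 3 of those arrays, at 6.84, 7.60 and 8.62 in placebo, 9.97, 10.02 and 6.70 in E2, 9.06, 10.37 and 9.0 in E2+MPA and 9.74, 9.87 and 10.38 in E2+P4.

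MYBPC1, a myosin-binding protein gene, had its highest mean in the arrays labelled E2+P4, which measured 8.14, 6.82 and 9.94, and measured 4.32, 4.52 and 4.57 in placebo, 7.0, 6.45 and 4.46 in E2 and 4.65, 7.12 and 6.56 in E2+MPA. CXCL13, a chemokine gene, measured 7.10, 4.98 and 8.02 in E2+P4, 3.70, 3.52 and 3.44 in placebo, 3.39, 4.90 and 3.38 in E2 and 3.39, 4.54 and 6.83 in E2+MPA. None of the 25 genes that varied most within groups belongs to the estrogen-induced list, the only list for which this was counted. PIP, a member of the androgen-induced list, was among the 25. It measured 8.78, 5.35 and 9.31 in E2+P4 and 5.93, 6.87 and 4.59 in placebo. In E2 it measured 4.79, 6.49 and 4.97, and in E2+MPA 4.55, 6.31 and 7.90. Among lists, the members of the interferon list varied together most within groups, with a mean correlation of 0.538 between pairs of its genes, followed by ribosome biogenesis genes at 0.421, mitosis genes at 0.366, hypoxia genes at 0.343 and DNA replication genes at 0.31, where random lists of matched level lay at 0.009 or less. Endothelial markers varied least, with an SD above that of only 0.3% of 10000 random lists.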
